A study of Arabidopsis thaliana with 46 samples.

How the data were processed

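Transcript levels were measured in shoots of Arabidopsis seedlings on 46 Affymetrix arrays, 1 per sample. The labels place the arrays in 16 groups of genotype and condition, 14 groups with 3 arrays and 2 groups with 2. Genotypes were the wild type Col-0 and 3 T-DNA insertion lines of WRKY1, named SALK_016954, SALK_136009 and SALK_070989. The arrays fall into 4 experiments, each with its own Col-0 arrays, and SALK_070989 and Col-0 were both grown in 7 conditions.

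RNA was isolated with a column kit and labelled with an in vitro transcription kit for 3′ expression arrays, per the labels' protocols. The authors deposited 1 table of background-corrected, normalized and summarised probe set values made with GCRMA, per the submitters' processing notes. The GCRMA version, and whether all arrays were processed in one run, are not given in the sources used here. That the deposited values are on a log2 scale was inferred from their range of 2.23 to 14.63. GCRMA sets probe sets without signal to nearly one value, and 26.4% of all values lay within 0.01 of the lowest. A difference against a group at that level is therefore a lower bound. Because normalization over arrays brings the distributions together, a change of most transcripts in one direction would not be seen. The number of arrays limits the precision, and no depth applies to them.

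The table holds 22810 probe sets, of which 64 are AFFX controls. Probe sets whose highest group mean exceeded 4 on the log2 scale were kept, 14288 of the 22746 that are not controls. Gene names came from the platform's annotation table, which lists 14016 probe sets, 13513 with 1 gene and 503 with several, and does not list 8794. Of the 13513, 13484 matched a locus tag of the TAIR10.1 gene table. Among the kept probe sets, 7668 (53.7%) carry 1 gene name, and the 6620 others were tested and counted but are unnamed here. Locus codes are used where the annotation gives no symbol. The annotation lists the probe set of AT2G04880 under the symbol ZAP1, which is called WRKY1 here after the title of the study.

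All tests used R 4.3.3 and limma 3.58.1. A linear model with 16 group means was fitted to all arrays (30 residual and 4.97 prior degrees of freedom). The 22 contrasts were moderated with eBayes and adjusted by Benjamini-Hochberg over the kept probe sets, with a threshold of 0.05. Values after ± are standard errors of a log2 difference unless an SD is named. Each interaction is a difference of differences within the same fit. Figures were drawn with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

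The groups, contrasts, filter, tests, alternatives, 17 gene lists and the rule for named genes were fixed before the data were examined. A further 17 lists were made from gene names of the annotation before any difference had been computed. Of all lists, 3 had no measured member and 7 had 1 or 2. The other 24 were tested with limma's camera at a preset correlation of 0.01, using for each gene the probe set with the highest mean, and adjusted within each comparison. The same tests were repeated with an estimated correlation. For lists fixed before the data were examined, counts are also given adjusted over the list alone. A list of genes typical of seeds was written only after some of its members' values had been seen.

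The rule for named genes took the 10 highest and 10 lowest differences past the threshold whose arrays did not overlap between the groups. For the mean of 7 conditions the sign had to hold in each condition, and for genes called in all 3 lines the ranking used the smallest difference of the lines. Interactions gave 5 genes in each direction. Each gene list gave up to 4 members with the smallest adjusted p. Fewer are printed where fewer sufficed.

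On simulated arrays with 14288 probe sets, the steady contrast of SALK_070989 recovered 49.3%, 95.5% and 98.5% of probe sets changed by 0.5, 1 and 2 on the log2 scale. The interaction of nitrogen and genotype recovered 11.9%, 74.6% and 100%, and the interaction of nitrogen, light and genotype 0%, 25.4% and 92.4%. With camera, 1 shifted list of 30 genes was called and 0 of 50 unshifted lists were. The simulated genes varied independently, so this run could not show false calls that arise from correlation between genes.

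Alternatives were no filter, a filter at 6 (10884 probe sets), a further quantile normalization, eBayes with a trend and robust settings, the replicate number as a block, a fit to only the groups compared, and leaving out each array in turn. List tests without Col-0 dark N-absent replicate 1, and of the cold and dehydration list without its members in the seed-type list, were added after the data had been seen. Scan dates were not used here.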

Results

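Arabidopsis seedlings were grown on plates for 14 days in a cycle of 16 h light and 8 h dark at 22 °C and 50 µmol m-2 s-1, and shoots were harvested 2 h after the lights came on. In the steady experiment, Col-0 and the 3 insertion lines of WRKY1 stayed on full medium. In the nitrogen experiment, seedlings raised on 1 mM KNO3 were moved for 2 h to medium with 20 mM KNO3 and 20 mM NH4NO3 (N-rich) or with 20 mM KCl (N-absent). In the light experiment, plates were wrapped in foil from the start of the preceding day until harvest (dark) or left in the normal cycle (light). The combined experiment joined darkness with the presence or absence of nitrogen (dark N-rich and dark N-absent). Its media and transfer times are not given in the sources used here, and its dark arrays have no light arrays of their own, so darkness and experiment cannot be told apart where the nitrogen response in the dark is set against that in the light. Its Col-0 groups have 2 arrays each, and every other group has 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

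The first question was whether the insertion lines carry less WRKY1 transcript, the gene named in the study's title. WRKY1 (AT2G04880) encodes a transcription factor of the WRKY family. Its level in Col-0 on full medium was 7.56 ± 0.18 (SD, n = 3), against 2.26 ± 0.04 in SALK_016954, 4.22 ± 0.27 in SALK_136009 and 2.57 ± 0.47 in SALK_070989. The differences from Col-0 were -5.31, -3.35 and -4.99, each ± 0.19, with limma adjusted p of 3.9e-21, 1.3e-14 and 3e-20. Over all conditions the 19 Col-0 arrays lay between 6.57 and 7.84 and the 21 SALK_070989 arrays between 2.23 and 3.26. Since 2.23 is the lowest value of the table, the differences for SALK_016954 and SALK_070989 are lower bounds. An exact permutation test of 3 against 3 arrays gave p = 0.1 for each line, the smallest value it allows. The position of the probes relative to the insertions is not given in the sources used here.

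**Figure D1:**
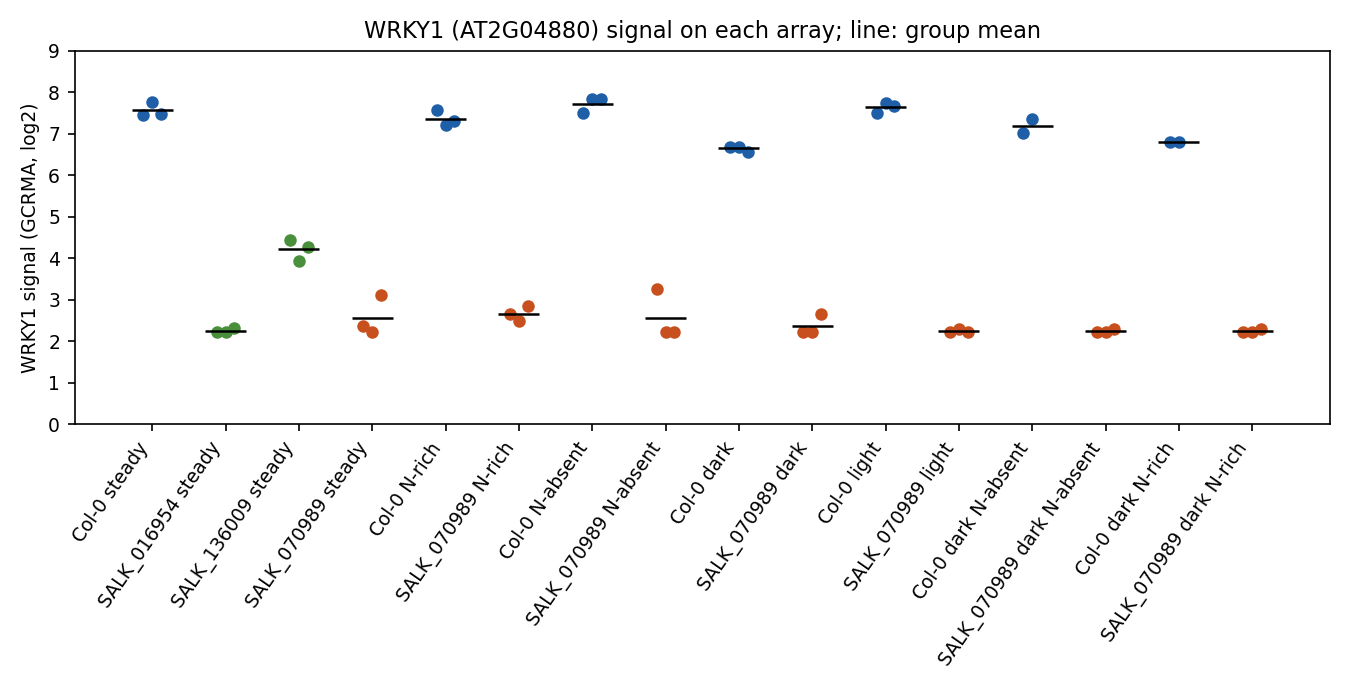
WRKY1 level (log2, vertical axis) in each array of the 16 groups (horizontal axis), with a line at each group mean. All 19 Col-0 arrays lie at or above 6.57, the 3 SALK_136009 arrays between 3.93 and 4.45, and all SALK_016954 and SALK_070989 arrays at or below 3.26.

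WRKY1 itself responded to darkness. In Col-0 it fell by 0.99 ± 0.19 in dark against light (limma adjusted p = 1.9e-05), from 7.64 to 6.65, while the N-rich medium gave -0.36 ± 0.19 (adjusted p = 0.18) in the light and -0.37 ± 0.24 (adjusted p = 0.3) in the dark. SALK_070989, near the lowest value throughout, differed by 0.12 between dark and light.

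Array medians ranged from 4.29 to 4.68. The dark groups had the lowest group medians, 4.3 in Col-0 and 4.31 in SALK_070989. SALK_070989 steady replicate 3 had a median of 4.37 where the other steady arrays had at least 4.54. Its GAPDH control signal was also more 3′-biased, 3.02 against at most 2.4 (3′ minus 5′, log2). Col-0 dark N-absent replicate 1 had a GAPDH bias of 2.91. A fit to only the groups compared leaves fewer arrays to estimate the spread and ended the call for 449 of 1158 gene and comparison pairs open to naming, among them every such gene of SALK_070989 against Col-0 in N-absent, where WRKY1 itself was at -5.15 with adjusted p = 0.051, and in N-rich every one other than WRKY1 (-4.7, 0.00083).

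On full medium the 3 lines shared a set of changed transcripts. In all of them 356 probe sets differed from Col-0 in the same direction, 274 higher and 82 lower, and 85 by at least 2-fold in every line. Among the transcripts that rose in SALK_016954, SALK_136009 and SALK_070989 were AT5G64190 (1.91, 2.05 and 1.99, each ± 0.22) and AT3G62950 (1.86, 2.68 and 2.88, ± 0.28), which encodes a CC-type glutaredoxin. SIS, a salt-induced gene for a serine-rich protein, rose by 1.67, 2.07 and 2.73 (± 0.22; limma adjusted p = 4.7e-06, 4e-08 and 7.6e-11). AT1G33055 rose by 1.76, 1.89 and 2.39, AT3G15450 by 1.54, 1.96 and 2.24, AT2G20670 by 1.54, 1.69 and 1.88, and AT1G02660 by 1.53, 1.91 and 2.47. Beside WRKY1, the deepest shared fall was that of AT4G12490, a member of the lipid transfer protein family, at -2.57, -3.27 and -4.04 (± 0.58). AT3G15310 followed at -2.2, -2.42 and -2.48, and AT4G12500, of the same family as AT4G12490, at -1.59, -1.76 and -2.32. M17, a late embryogenesis abundant gene, fell by 1.81, 1.39 and 2.08, from 4.32 ± 1 (SD, n = 3) in Col-0 steady. In the other Col-0 groups M17 was near the lowest value, between 2.24 and 2.6, with 2.25 in Col-0 light. AT5G15950, which encodes an S-adenosylmethionine decarboxylase, changed by -1.15, -1.49 and -2.04. AT3G44450, which encodes an inhibitor of the cryptochrome blue light receptors, changed by -1.14, -1.88 and -2.65. In SALK_016954 the call on AT4G12490 ended without Col-0 steady replicate 1 (-2.05, adjusted p = 0.078) or SALK_016954 steady replicate 2 or 3 (-2.36 and -2.12, adjusted p = 0.054 and 0.11). There the call on AT4G12500 ended without the same arrays (-0.87, -1.55 and -1.30, adjusted p = 0.29, 0.11 and 0.23), and with no filter (adjusted p = 0.061); in SALK_136009 it ended without Col-0 steady replicate 1 (-1.04, adjusted p = 0.12).

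All 3 lines were set against the same 3 Col-0 arrays, which raises their overlap. Unchanged groups simulated against a shared simulated control gave 0 shared calls in 100 draws with limma's moderated variances. At an unadjusted p under 0.05 the simulated groups gave a mean of 36.9 and a maximum of 51, where 1090 were observed. The real Col-0 arrays were not used in the simulation, and probe sets were drawn independently. A joint displacement of the real Col-0 arrays could therefore not enter these references. Independent lists of the same lengths would share 17.3 higher and 4.36 lower probe sets between SALK_016954 and SALK_136009, where 316 and 105 were observed. For SALK_016954 and SALK_070989 these were 19.1 and 8.81 against 280 and 91, and for SALK_136009 and SALK_070989 40.6 and 33.5 against 508 and 294. Across probe sets, which are not independent replicates, the effects of the lines correlated at 0.828, 0.696 and 0.741 for these pairs, where simulation gave 0.501. The covariances were 0.0706, 0.0685 and 0.0878 against a simulated 0.0162, differences of 0.0544, 0.0523 and 0.0716. The 3 Col-0 arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The shared count was 223 without Col-0 steady replicate 1, 237 without Col-0 steady replicate 2, and 223 and 164 without SALK_016954 steady replicates 2 and 3.

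The lines differed in how many transcripts changed. SALK_016954 had 468 changed probe sets (340 higher, 128 lower), 93 of them by at least 2-fold. A further quantile normalization gave 316 higher and 198 lower. BHLH101, a regulator of iron responses, rose by 1.61 ± 0.21 (limma adjusted p = 3.9e-06), AT2G29300 by 1.58 ± 0.20 and AT5G12050 by 1.53 ± 0.22, and QQS, a gene linked to starch content, fell by 1.29 ± 0.24. SALK_136009 had 1212 changed probe sets (725 higher, 487 lower), 212 of them by at least 2-fold. AT3G62550 rose there by 1.83 ± 0.29 and AT2G27420 fell by 1.84 ± 0.30. PORB, an enzyme of chlorophyll synthesis, rose by 1.09 ± 0.18 and WRKY22 by 1.16 ± 0.17. The SALK_016954 count was 299 and 281 without Col-0 steady replicates 1 and 2, 698 with SALK_016954 steady replicate 1 left out, and 253 and 184 without its replicates 2 and 3; it was 20 in a fit to only these groups. The SALK_136009 count was 636 without SALK_136009 steady replicate 2 and 433 in a fit to only these groups.

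SALK_070989 changed most on full medium, with 1784 probe sets (801 higher, 983 lower), 348 of them by at least 2-fold. AT3G62550 rose by 2.81 ± 0.29 (limma adjusted p = 1.1e-08), AT4G28703 by 2.67 ± 0.26 (3.2e-09) and AT4G27450 by 2.28 ± 0.23 (4.4e-09). AT3G44450 fell by 2.65 ± 0.23, AT2G27420 by 2.51 ± 0.30 and AT1G20070 by 2.26 ± 0.20. Of 6 measured genes of auxin signalling and synthesis, 3 rose, among them IAA29 (1.93 ± 0.26) and GH3.17 (0.93 ± 0.18), with a list median of 0.56 (camera adjusted p = 0.0014, and 0.0071 with an estimated correlation). Of 5 glucosinolate genes 3 fell, with a median of -0.73 and the same pair of adjusted p. UGT74B1, a glucosyltransferase of that pathway, fell by 0.88 ± 0.14 and AOP1 by 0.73 ± 0.15. The leucine breakdown genes IVD and MCCA rose by 0.76 ± 0.15 and 0.82 ± 0.17, PORB by 1.45 ± 0.18 and WRKY22 by 1.37 ± 0.17. HYH, a bZIP factor of light signalling, fell by 1.14 ± 0.19, and the senescence-associated sugar transporter gene SAG29 by 1.59 ± 0.30. The remaining auxin gene, YUC2 (0.68 ± 0.22), lost its call without Col-0 steady replicate 3 (0.35, adjusted p = 0.36), or without SALK_070989 steady replicate 1 or 3 (0.61 and 0.68, adjusted p = 0.11 and 0.095), and with no filter (adjusted p = 0.071). Without SALK_070989 steady replicate 3, the array with the 3′ bias, GTR1, the remaining glucosinolate gene to fall, was at -0.87 with adjusted p = 0.054. The balance turned to 921 higher and 815 lower after a further quantile normalization, 721 and 480 without SALK_070989 steady replicate 3, and 356 and 289 in a fit to only these groups, which called 645.

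The nitrate response list, fixed before the data were examined, had 3 measured members of 32. In each line 2 of them rose, and 2 when adjusted over the list alone. AT1G25550 and AT1G68670, which encode related MYB-type repressors known from nitrate signalling, rose by 1.01 and 0.84 in SALK_016954, 1.12 and 1.01 in SALK_136009, and 1.26 and 0.94 in SALK_070989 (each ± 0.15). AT1G64190, a phosphogluconate dehydrogenase gene, gave -0.24 in SALK_016954, -0.16 in SALK_136009 and -0.27 in SALK_070989, none past the threshold. Camera called the list in each line, with adjusted p of 0.025, 0.017 and 0.0094. With an estimated correlation these were adjusted p = 0.13, adjusted p = 0.1 and adjusted p = 0.046, so that the call held in SALK_070989 alone.

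After 2 h without nitrogen, 1146 probe sets differed between SALK_070989 and Col-0, 597 higher and 549 lower, and 135 by at least 2-fold. AT5G53710 rose by 2.26 ± 0.23 (limma adjusted p = 4.8e-08) and PUB19, a U-box ubiquitin ligase gene, by 2.04 ± 0.36. AT3G05640 and AT1G49500 both rose by 1.72 and AT1G49450 by 1.66 ± 0.30. AT1G76960 fell by 3.62 ± 0.41 (adjusted p = 3.5e-07) and CML41, a calmodulin-like gene, by 2.11 ± 0.25 (1e-06). The spread behind these SE is pooled over all groups, and the N-absent groups varied more in some of these genes. AT1G76960 was at 6.24 ± 1.65 (SD, n = 3) in Col-0, and AT5G53710 had SDs of 0.52 in Col-0 and 0.79 in SALK_070989. AT1G19960 fell by 1.75, and by 1.06 without Col-0 N-absent replicate 3, AT3G48640 by 1.7, PME61, a pectin methylesterase gene, by 1.62 and AT2G36970 by 1.59. PPDK, pyruvate phosphate dikinase, fell by 0.85 ± 0.16, the only member of 9 in the dark and carbon starvation list to pass (1 adjusted over the list alone; camera adjusted p = 0.023, but adjusted p = 0.27 with an estimated correlation).

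Some autophagy genes fell in SALK_070989 without nitrogen, but the list's call did not hold with an estimated correlation. Of 7 in the autophagy list 4 fell, and 6 adjusted over the list alone, with a median of -0.36. Camera gave adjusted p = 0.00013, and adjusted p = 0.073 with an estimated correlation. ATG8E, which encodes a ubiquitin-like protein of the autophagosome, was at -0.76 ± 0.19. In the wider list of ATG8 and ATG3 genes 5 of 10 fell (camera adjusted p = 6.4e-06, and adjusted p = 0.073 with an estimated correlation). Without Col-0 N-absent replicate 3, ATG8E was at -0.59 (adjusted p = 0.093) and ATG8D, at -0.91 ± 0.21 with all arrays, at -0.71 (0.068). ATG8E also lost its call without SALK_070989 N-absent replicate 1 (-0.57, adjusted p = 0.089). Of the nitrate response genes 2 rose (3 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.073 with an estimated correlation). Both lost their calls when 1 array was left out. AT1G25550 (0.60 ± 0.15) lost its call without Col-0 N-absent replicate 1 or SALK_070989 N-absent replicate 1 (0.53 and 0.45, adjusted p = 0.051 and 0.088). AT1G68670 lost it without Col-0 N-absent replicate 3 or SALK_070989 N-absent replicate 1 or 2 (0.32, 0.47 and 0.33, adjusted p = 0.3, 0.11 and 0.26). The total was 508 without Col-0 N-absent replicate 3, 723 and 668 without SALK_070989 N-absent replicates 1 and 2, and 0 in a fit to only these groups, where limma gave 2202 at an unadjusted p under 0.05. The 2 arrays numbered 3 deviated together from their group means, and without both, an alternative chosen after the data were seen, 465 were called.

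On N-rich medium 393 probe sets differed, 232 higher and 161 lower, and 69 by at least 2-fold. AT5G53710 again led, at 1.99 ± 0.23 (limma adjusted p = 1.5e-06), followed by AT5G28630 (1.67 ± 0.31), AT5G24080 (1.56 ± 0.20) and AT1G05670 (1.42 ± 0.13, adjusted p = 3.9e-09). CML37, a calmodulin-like gene, rose by 1.35 ± 0.20. AT5G37990 fell by 1.98 ± 0.43 and AT4G14060 by 1.83 ± 0.37. No gene list passed camera with an estimated correlation. Without SALK_070989 N-rich replicate 3, AT5G37990 was at -1.50 (adjusted p = 0.095). The total was 193 and 150 without Col-0 N-rich replicates 1 and 3, 172 and 157 without SALK_070989 N-rich replicates 2 and 3, and 1 in a fit to only these groups (2327 at an unadjusted p under 0.05).

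In extended darkness 372 probe sets differed between SALK_070989 and Col-0, 208 higher and 164 lower, and 70 by at least 2-fold. AT2G19970 rose by 2.19 ± 0.19 (limma adjusted p = 9.8e-10) and CCOAMT, a caffeoyl-CoA methyltransferase gene, by 1.69 ± 0.21 (1.8e-06). XTH18, a gene of xyloglucan remodelling in the cell wall, rose by 1.62 ± 0.30 and AT1G77640 by 1.45 ± 0.19. AT1G43590 was lower at -1.94 ± 0.17, AT3G21670, a member of the nitrate and peptide transporter family, at -1.82 ± 0.21 (adjusted p = 3.4e-07), and AT2G25510 at -1.67 ± 0.21. AT2G07751 and QQS fell to differences of -1.46 and -1.28, and ECS1, a cell wall protein gene of the defence list, to -1.23 ± 0.13. Among 11 beta-glucosidases BGLU33 alone fell, by 0.61 ± 0.13 (camera adjusted p = 0.024, and adjusted p = 0.17 with an estimated correlation). The total was 218 without Col-0 dark replicate 1, 219 without SALK_070989 dark replicate 1, 648 with no filter and 12 in a fit to only these groups.

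In the light controls of the same experiment 802 probe sets differed, 545 higher and 257 lower, and 181 by at least 2-fold. EXLA1, an expansin-like gene, rose by 3.23 ± 0.45 (limma adjusted p = 9.6e-06), and EXLA2 by 1.55 ± 0.23. AT3G19680 rose by 2.37, AT1G50040 by 2.11, AT4G28703 by 2.09, AT2G30930 by 2.08 and AT3G62550 by 1.95, and the bZIP gene BZIP34 by 1.76 ± 0.26. AT2G27420 was lower at -2.07 ± 0.30, AT5G54130 at -1.57 and AT2G15020 at -1.49. Of 9 dark and carbon starvation genes 3 rose (4 adjusted over the list alone), led by IVD at 1.02 ± 0.15. Their median was 0.31, with camera adjusted p = 0.00047, and adjusted p = 0.083 with an estimated correlation. Of the other members to rise, BZIP53 (0.54 ± 0.12) lost its call without SALK_070989 light replicate 3 (0.41, adjusted p = 0.066). MCCA (0.69 ± 0.17) lost it without Col-0 light replicate 1 or SALK_070989 light replicate 1 or 2 (0.60, 0.55 and 0.59, adjusted p = 0.093, 0.1 and 0.084). The total was 436 without Col-0 light replicate 1 and 522 without SALK_070989 light replicate 1.

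The light condition repeats the stated steady condition on separate arrays of both genotypes. Across probe sets the effects of SALK_070989 in steady and light correlated at r = 0.66, with a slope of light on steady of 0.53. Both called 500 probe sets in the same direction and 5 in opposite directions, which is 28% of the steady and 62.3% of the light calls. AT4G28703, AT3G62550 and AT2G27420 were among the named genes of both. Of the genes shared by the 3 lines on full medium, SIS (1.44), AT1G02660 (1.63), AT3G62950 (1.11), AT1G33055 (1.09), AT5G64190 (0.92), AT5G15950 (-1.14) and AT3G44450 (-1.2) were also called in the light. There AT3G15450 was at 0.77 (limma adjusted p = 0.052), AT2G20670 at 0.37 (0.42), AT4G12490 at -0.78 (0.56), AT3G15310 at -0.94 (0.09), AT4G12500 at -0.31 (0.82) and M17 at 0.47 (0.4), none past the threshold.

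**Figure D2:**
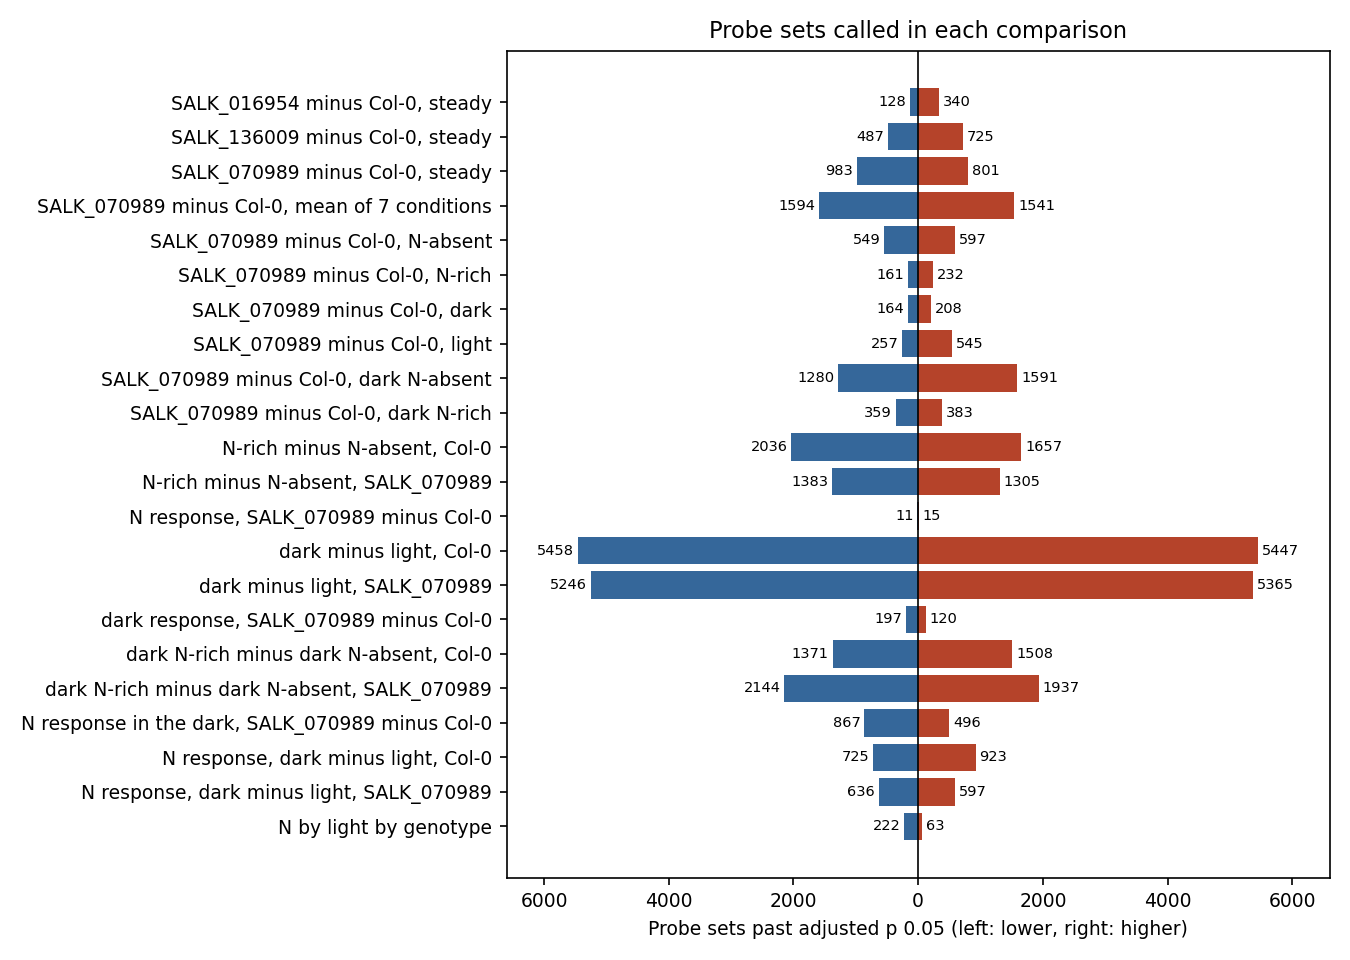
Number of probe sets called by limma (adjusted p under 0.05) as higher or lower in each of the 22 comparisons. Bars run from 0, to the right for higher and to the left for lower. The dark against light comparisons reach 5447 higher and 5458 lower in Col-0, and 5365 and 5246 in SALK_070989. The difference between these responses reaches 120 and 197.

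Darkness combined with nitrogen medium gave the largest single differences between the genotypes. By number of changed probe sets only dark N-absent exceeded the other conditions, while dark N-rich had 742, fewer than the 1784 of steady. In dark N-absent 2871 probe sets differed, 1591 higher and 1280 lower, and 529 by at least 2-fold. More than 8-fold higher were 52, against at most 2 in the steady, nitrogen, dark and light comparisons of SALK_070989. AT3G02480 rose by 8.42 ± 0.69 (limma adjusted p = 7.9e-12), AT3G15670, of the late embryogenesis abundant family, by 7.52 ± 0.23 (2.4e-24), AT5G07330 by 7.43 ± 0.20 and AT5G66780 by 7.38 ± 0.32. AT3G54940, LEA18 and ICL rose by 7.07, 7.06 and 7.06. ICL encodes isocitrate lyase, which serves the conversion of stored lipid to sugar. In Col-0 the means of AT3G15670, AT5G07330, AT5G66780, AT3G54940 and LEA18 lay between 2.23, the lowest value, and 2.31, so that their differences are lower bounds. AT3G02480 (2.94) and ICL (4.39) lay above it.

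A list of 51 seed-type genes was chosen after values had been seen; a probe set named 22, and 19 passed the filter, 14 of them only through SALK_070989 groups. Of the 19, 18 rose in dark N-absent (median 4.02) and 16 in dark N-rich (median 2.01). With no filter 19 and 15 of the 22 rose (medians 3.66 and 1.68). In dark alone 0 rose and 2 fell, with a median of 0. In N-absent, N-rich and light limma called 0, and in steady M17 alone, which fell by 2.08. Only 5 of the 19 had a mean above 4 in any Col-0 group. In SALK_070989 ICL reached 11.45 in dark N-absent and 11.48 in dark N-rich, AT3G15670 9.75 and 8.37, LEA18 9.37 and 8.33, and AT3G01570 8.09 and 7.61. The Col-0 dark N-rich replicates differed in ICL, at 4.04 and 7.56. Without the 98 probe sets over 4-fold higher in the mutant in either combined condition, a count made after they had been seen, 2773 remained in dark N-absent and 658 in dark N-rich.

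**Figure D3:**
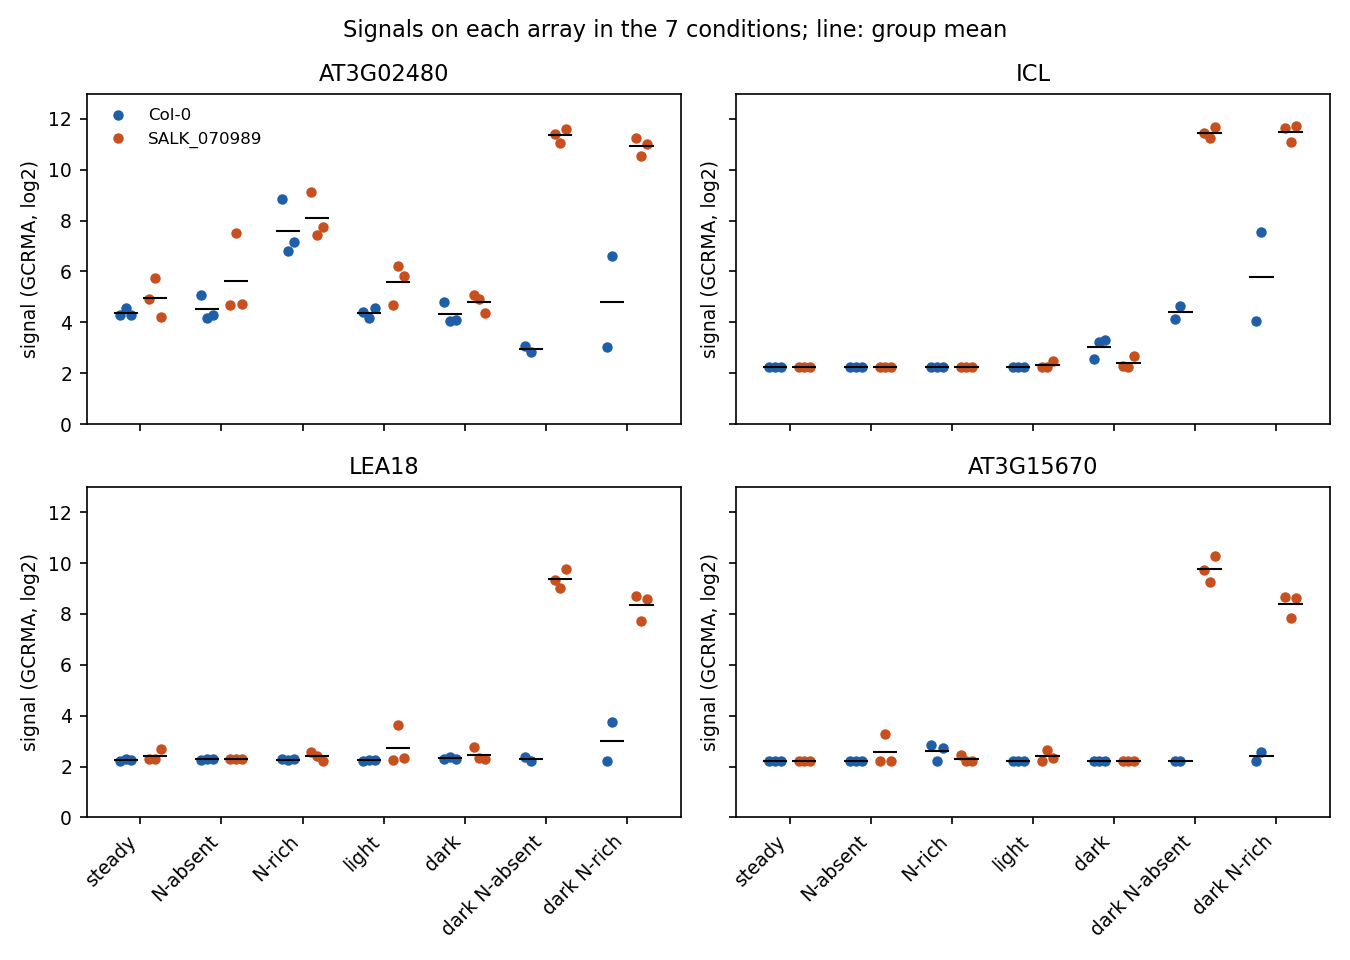
Levels (log2, vertical axis) of AT3G02480, ICL, LEA18 and AT3G15670 in each array of Col-0 and SALK_070989 in 7 conditions (horizontal axis), with a line at each group mean. In dark N-absent and dark N-rich the SALK_070989 arrays lie far above the Col-0 arrays, with ICL means of 11.45 and 11.48, and in the other conditions limma called none of the 4 genes, though AT3G02480 was higher in the mutant by 0.46 to 1.19.

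Nuclear genes of the photosynthetic apparatus were higher in SALK_070989 in dark N-absent, while plastid-encoded genes had a negative median. Of 30 nuclear photosynthesis and chlorophyll genes 20 rose, with a median of 0.47 (camera adjusted p = 1.2e-12, and 0.026 with an estimated correlation). Of 66 plastid-encoded transcripts 2 fell, petN (-1.20 ± 0.39) and psbA (-0.68 ± 0.24), and the median was -0.53 (camera adjusted p = 4.2e-05, but adjusted p = 0.41 with an estimated correlation). The petN call ended without Col-0 dark N-absent replicate 1 (-0.75, adjusted p = 0.39) or SALK_070989 dark N-absent replicate 2 or 3 (-1.05 and -0.93, adjusted p = 0.087 and 0.14). The psbA call ended without either Col-0 array (-0.51 and -0.86, adjusted p = 0.34 and 0.054) or SALK_070989 dark N-absent replicate 2 or 3 (-0.69 and -0.40, adjusted p = 0.068 and 0.28). Among the nuclear genes PSB27, a photosystem II assembly gene, rose by 0.81 ± 0.08, LIL3:2 by 0.87 ± 0.11, CHLM by 0.70 ± 0.09 and NdhL by 1.27 ± 0.18. All 3 Calvin cycle genes rose (3 adjusted over the list alone; median 0.54; camera adjusted p = 0.0013, and 0.032 with an estimated correlation), among them PRK, phosphoribulokinase, by 0.87 ± 0.13. Of 4 chlorophyll synthesis genes 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0015, and 0.032 with an estimated correlation). Of 4 light harvesting genes 2 rose, and 2 adjusted over the list alone (camera adjusted p = 0.023, but adjusted p = 0.11 with an estimated correlation and 0.058 after a further quantile normalization). RCA, SBPASE and PRK of the Calvin cycle list, and CHLM, CHLI2 and PORB of the chlorophyll list, are also among the 30 nuclear genes. So are LHCB4.1, LHCB4.2, LHCB4.3 and PSBY of the light harvesting list, and the calls of these lists are not separate results. Of 12 cold and dehydration genes 5 rose, LEA18 and LEA4-5 by 7.06 and 5.80, LEA by 4.73 and DI21 by 3.04, and the median was 0.06 (camera adjusted p = 4.2e-05, and 0.029 with an estimated correlation). LEA18 and LEA are also in the seed-type list, so this is not a separate result; of the other 10 genes 3 rose, at a median of -0.05 (unadjusted camera p = 0.027, and 0.16 with an estimated correlation, in a test chosen after the result was seen). Of 9 genes of branched-chain amino acid and lysine breakdown 5 rose and 1 fell, MCCB by 0.94 ± 0.13 and D2HGDH by -0.73 ± 0.16 (camera adjusted p = 0.021, but adjusted p = 0.13 with an estimated correlation). Col-0 dark N-absent replicate 1 had a GAPDH 3′ bias of 2.91, against 2.22 in the other Col-0 array and 2.14 to 2.33 in the mutant arrays. Without it, an alternative chosen after the data were seen, 12 of the 30 photosynthesis genes rose (camera adjusted p = 2e-09, and 0.035 with an estimated correlation). The Calvin cycle and chlorophyll synthesis lists then had camera adjusted p = 0.018 each, but adjusted p = 0.11 with an estimated correlation. The lists of light harvesting and of branched-chain amino acid breakdown lost their calls, both at camera adjusted p = 0.079.

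Defence genes went the other way. Of 24 in the list of defence, wounding and jasmonate genes 9 fell in dark N-absent, with a median of -0.44 (camera adjusted p = 0.00014, and 0.026 with an estimated correlation). Without Col-0 dark N-absent replicate 1, the array with the GAPDH bias of 2.91, 2 fell (camera adjusted p = 0.0021, but adjusted p = 0.058 with an estimated correlation). OPCL1, an enzyme gene of jasmonate synthesis, fell by 0.91 ± 0.18. PUB22, a ubiquitin ligase gene of defence signalling, was at -0.95 ± 0.24, and at -0.87 (adjusted p = 0.072) without Col-0 dark N-absent replicate 1. Of 6 WRKY genes 3 fell, WRKY1 included (5 adjusted over the list alone; camera adjusted p = 0.00041, and 0.026 with an estimated correlation). Without WRKY1 the other 5 gave an unadjusted camera p of 0.027, and 0.11 with an estimated correlation, in a test chosen after the result was seen. Among single genes AT3G28510 fell by 3.24 ± 0.50, AT1G26390 by 2.51 ± 0.36 and AT5G24240 by 2.2 ± 0.23. The total was 1286 without the same array, Col-0 dark N-absent replicate 1, which leaves a single Col-0 array assumed to vary like the other groups, and 1251 in a fit to only these groups.

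In dark N-rich 742 probe sets differed, 383 higher and 359 lower, 203 by at least 2-fold and 29 more than 8-fold higher. AT3G02480 rose by 6.11 ± 0.69 (limma adjusted p = 5.1e-08), AT3G15670 by 5.98 ± 0.23 and ICL by 5.68 ± 0.42 (7e-13). LEA18 and AT5G66780 both rose by 5.34. The 2 Col-0 dark N-rich arrays lay far apart in AT3G02480 (SD 2.54) and ICL (SD 2.49). Without Col-0 dark N-rich replicate 1 AT3G02480 was at 4.32 and ICL at 3.91, and without replicate 2 at 7.9 and 7.44, all still called. The glutathione transferase gene GSTU26 rose by 2.1 ± 0.26 and XTH19 by 1.88 ± 0.32. The fall of AT2G30670 was -1.72 ± 0.24, that of AT1G26390 -1.67 ± 0.36 and that of QQS -1.59 ± 0.27. Without replicate 1 AT2G30670 was at -2.68 and QQS at -1.04, and without replicate 2 AT2G30670 was at -0.77, all still called. Of 12 cold and dehydration genes 4 rose, with a median of -0.08 and a mean of 0.97, so that the median and the camera call (higher, adjusted p = 0.0017) differ in sign; with an estimated correlation adjusted p = 0.2. LEA18 and LEA are also in the seed-type list, and of the other 10 genes 2 rose. EFR, a receptor gene for a bacterial elongation factor, rose by 1.26 ± 0.25. The total was 479 and 492 without SALK_070989 dark N-rich replicates 2 and 3, and 68 in a fit to only these groups.

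Averaged over the 7 conditions, 3135 probe sets differed between SALK_070989 and Col-0, 1541 higher and 1594 lower. Of these 41 differed by at least 2-fold and 575 had the same sign in every condition (236 higher, 339 lower). AT3G02480, LEA18 and LEA4-5 led the rises at 2.62 ± 0.24, 1.91 ± 0.10 and 1.79 ± 0.16, carried by the combined conditions, and AT4G28703 rose by 1.34 ± 0.10 (limma adjusted p = 1.6e-12). AT4G12490 fell by 1.33 ± 0.23, AT4G20300 by 1.29 ± 0.05 (8.9e-20), QQS by 1.1 ± 0.09 (4.1e-11) and AT2G25510 by 0.91 ± 0.08. WRKY1, AT4G20300 and 1 unnamed probe set were the only ones called in each of the 7 conditions. AT4G20300 is singled out here after its values were seen. It was at -1.67 ± 0.14 in SALK_070989 on full medium, but at -0.09 in SALK_016954 and -0.14 in SALK_136009.

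Some members of gene lists changed in this mean, while none of the lists below was called with an estimated correlation. XTH19 (0.74 ± 0.11), EXPA20 (0.41 ± 0.06) and EXPA9 (0.45 ± 0.08) were among 7 of 17 expansin and xyloglucan genes that rose, with 1 that fell (camera adjusted p = 0.015, and adjusted p = 0.17 with an estimated correlation). Of 7 SWEET sugar transporters 3 fell, SWEET1 by 0.36 ± 0.06 and SWEET13 by 0.61 ± 0.13 (camera adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation). Of 4 chlorophyll synthesis genes 3 rose and 4 adjusted over the list alone, PORB by 0.42 ± 0.07 (camera adjusted p = 0.012, and adjusted p = 0.12 with an estimated correlation). Of the 3 nitrate response genes 2 rose, and 2 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation).

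The next question was how the shoots responded to nitrogen supply in the light, and whether that response differed without WRKY1. In Col-0, 3693 probe sets (25.8%) differed between N-rich and N-absent, 1657 higher and 2036 lower, and 664 by at least 2-fold. AT1G05575 rose by 5.19 ± 0.22 (limma adjusted p = 4.6e-19). The CC-type glutaredoxin genes AT4G15680, AT4G15660, AT4G15700 and AT4G15690 rose by 4.37, 4, 3.58 and 3.53, AT3G19030 by 3.66, AT4G01870 by 3.33 and PUB19 by 3.31. AT1G70270 fell by 3.13 ± 0.17, AT4G17670 by 2.90 ± 0.25, AT3G19680 by 2.73 and CML41 by 2.32. NRT2.5, a high-affinity nitrate transporter gene of nitrogen-starved plants, fell by 2.17 ± 0.44 (adjusted p = 0.00029).

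Of the 3 nitrate response genes 2 rose in Col-0, and 3 adjusted over the list alone, AT1G25550 by 2.86 ± 0.15 and AT1G68670 by 1.75 ± 0.15 (camera adjusted p = 2.7e-05, and 0.0025 with an estimated correlation). Autophagy genes fell, 6 of 7 and 6 adjusted over the list alone, with ATG8E at -0.91 ± 0.19 and APG8H at -0.59 ± 0.12 (camera adjusted p = 0.0055, but adjusted p = 0.21 with an estimated correlation). In the wider list of ATG8 and ATG3 genes 9 of 10 fell (camera adjusted p = 0.00034, but adjusted p = 0.21 with an estimated correlation). Of 9 purine and ureide recycling genes 3 fell, allantoinase (ALN) at -1.77 ± 0.27, allantoate amidohydrolase (AAH) at -0.85 ± 0.13 and the asparaginase gene ASPGB1 at -1.60 ± 0.33 (camera adjusted p = 0.025, but adjusted p = 0.21 with an estimated correlation). WRKY6 rose by 2.15 ± 0.25 and WRKY53 by 1.74 ± 0.23. A fit to only these groups called 1495.

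SALK_070989 responded with 2688 probe sets (18.8%), 1305 higher and 1383 lower, and 690 by at least 2-fold. AT4G15680 rose by 5.19 ± 0.25, AT1G05575 by 5.05 ± 0.22, AT4G15690 by 4.28 and AT5G16960 by 4.17. AT5G38910 fell by 3.64 ± 0.41, the glucosyltransferase gene UGT72E2 by 3.34 ± 0.40 and AT3G13610, an enzyme gene of coumarin synthesis, by 3.32 ± 0.51. Of the nitrate response genes 2 rose, and 2 adjusted over the list alone, AT1G25550 by 2.58 and AT1G68670 by 1.28, each ± 0.15 (camera adjusted p = 4.5e-05, and 0.0033 with an estimated correlation). A fit to only these groups called 1326. Across probe sets the responses of the genotypes correlated at r = 0.77. Both called 1694 in the same direction and 8 in opposite directions, 45.9% of the Col-0 and 63% of the SALK_070989 calls.

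The nitrogen response itself differed between the genotypes in 26 probe sets, 15 higher and 11 lower in SALK_070989. AT5G39670, a calcium-binding protein gene, responded more positively by 1.66 ± 0.27 (limma adjusted p = 0.0024), CML37 by 1.63 ± 0.28 (0.0042), AT3G48640 by 1.59 ± 0.25 and AT1G05670 by 1.42 ± 0.18 (4.7e-05). The lowest was AT2G43610 at -2.49 ± 0.50 (adjusted p = 0.023), whose call ended without Col-0 N-rich replicate 1 or 3 (-2.30 and -2.27, adjusted p = 0.076 and 0.064), SALK_070989 N-rich replicate 3 (-2.13, 0.065) or SALK_070989 N-absent replicate 3 (-2.23, 0.051). No gene of the 10 in the ATG8 and ATG3 list was called (limma), although camera placed the list higher (median 0.27, adjusted p = 0.032, but adjusted p = 0.54 with an estimated correlation). The count was 17 without Col-0 N-rich replicate 1 or 3, 43 without Col-0 N-rich replicate 2, 66 and 63 without Col-0 N-absent replicates 2 and 3, and 112 without SALK_070989 N-absent replicate 1, where 37 were higher and 75 lower. In a fit to only these groups it was 0, where limma gave 1208 at an unadjusted p under 0.05.

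Extended darkness changed most of the measured transcripts. In Col-0, 10905 probe sets (76.3%) differed between dark and light, 5447 higher and 5458 lower, and 6235 by at least 2-fold. AT1G19530 rose by 8.98 ± 0.17 (limma adjusted p = 1.4e-31), AT1G72060 by 7.46, COR27, a cold- and light-regulated gene, by 7.45 ± 0.12, AT1G19540 by 7.37 and the glutamine amidotransferase gene GAT1_2.1 by 7.18 ± 0.35. GSTU20 fell to a difference of -7.87 ± 0.17, BCAT4, an enzyme gene of methionine-derived glucosinolate synthesis, to -7.8 ± 0.14, and LrgB, a plastid glycolate transporter gene, to -7.09 ± 0.23.

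All 9 dark and carbon starvation genes rose in Col-0 (9 adjusted over the list alone), with a median of 4.36 (camera adjusted p = 5.6e-06, and 0.0099 with an estimated correlation). MCCA and MCCB, subunits of methylcrotonyl-CoA carboxylase in leucine breakdown, rose by 5.85 ± 0.17 and 4.36 ± 0.11, IVD by 5.32 ± 0.15 and AT4G33150, the first enzyme gene of lysine breakdown, by 6.31 ± 0.18. Nuclear photosynthesis and chlorophyll genes fell, 27 of 30 with 1 that rose, at a median of -1.64 (camera adjusted p = 2.3e-09, and 0.027 with an estimated correlation). NdhN was at -5.56 ± 0.12 and CaS at -4.70 ± 0.09. Of 5 glucosinolate genes 4 fell, at a median of -3.04 (camera adjusted p = 0.0061, and 0.027 with an estimated correlation). All 3 Calvin cycle genes fell (3 adjusted over the list alone), SBPASE by 3.56 ± 0.12 and RCA by 2.64 ± 0.08 (camera adjusted p = 0.0066, but adjusted p = 0.098 with an estimated correlation). All 7 autophagy genes rose (7 adjusted over the list alone), ATG8B by 3.12 ± 0.16 (camera adjusted p = 0.0047, but adjusted p = 0.13 with an estimated correlation). All 4 light harvesting genes fell (4 adjusted over the list alone), LHCB4.3 by 2.77 ± 0.17, and 3 of 4 chlorophyll synthesis genes (3 adjusted over the list alone), CHLI2 by 3.61 ± 0.17. Both lists had camera adjusted p = 0.039, and with an estimated correlation adjusted p = 0.13 and adjusted p = 0.15. The Calvin cycle genes and the named LHCB4.3 and CHLI2 are also among the 30 nuclear photosynthesis genes. The falls of these smaller lists are therefore not separate results. WRKY22 rose by 4.48 ± 0.17 and the clock gene GI by 2.1 ± 0.16, and HYH fell by 4.18 ± 0.19.

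SALK_070989 responded to darkness with 10611 probe sets (74.3%), 5365 higher and 5246 lower, and 5724 by at least 2-fold. AT1G19530 rose by 8.92 ± 0.17 and COR27 by 7.14 ± 0.12, while BCAT4 and GSTU20 fell by 7.92 and 7.87. The same 9 dark and carbon starvation genes rose, with a median of 3.94 (9 adjusted over the list alone; camera adjusted p = 8.6e-06, and 0.013 with an estimated correlation). Of 30 nuclear photosynthesis genes 28 fell (median -1.65; camera adjusted p = 4.8e-11, and 0.016 with an estimated correlation). Across probe sets the responses of the genotypes correlated at r = 0.97, with 9860 called in both in the same direction and 10 in opposite directions. The slope of the SALK_070989 response on that of Col-0 was 0.9.

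**Figure D4:**
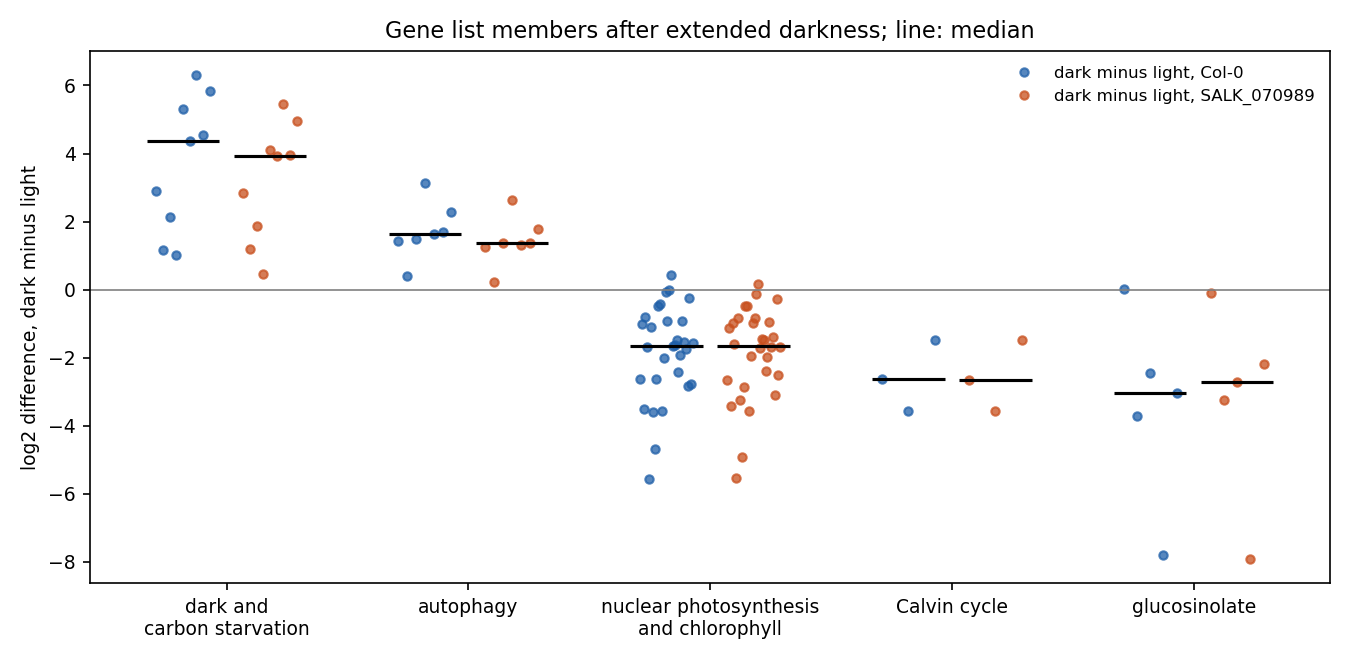
Log2 difference of dark minus light (vertical axis) for the measured members of 5 gene lists in Col-0 and SALK_070989, with a line at each list's median. The dark and carbon starvation genes rise in both genotypes, with medians of 4.36 and 3.94, and the nuclear photosynthesis and chlorophyll genes fall, with medians of -1.64 and -1.65.

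The dark response differed between the genotypes in 317 probe sets, 120 higher and 197 lower in SALK_070989, and 154 of them by at least 2-fold. AT2G27420 responded more positively by 2.13 ± 0.43 (limma adjusted p = 0.0044), CCOAMT by 1.66 ± 0.29 (0.0014) and AT2G46735 by 1.61 ± 0.21 (1.2e-05). AT3G62550 was at -2.33 ± 0.41 (0.0014), AT2G07751 at -2.05, AT3G19680 at -2.04 ± 0.43 and BZIP34 at -2.00 ± 0.36. AT2G27420 was the lowest named gene, and AT3G62550, AT3G19680 and BZIP34 were among the highest, of SALK_070989 against Col-0 in the light, beside WRKY1. The dark and carbon starvation genes had a weaker rise in SALK_070989, with a median difference of -0.56 (camera adjusted p = 6.9e-06, and 0.02 with an estimated correlation). Single genes passed in 2 cases, and in 6 adjusted over the list alone, led by IVD at -1.22 ± 0.21 (limma adjusted p = 0.001). With all arrays IVD, BZIP53 and MCCA were already higher in SALK_070989 than in Col-0 in the light. A weaker rise therefore does not by itself show lower levels in the dark. No autophagy gene of 7 passed (limma; 0 adjusted over the list alone), at a median of -0.30 (camera adjusted p = 0.04, but adjusted p = 0.41 with an estimated correlation and 0.052 after a further quantile normalization). The interaction for WRKY1 was 1.12 ± 0.27 (limma adjusted p = 0.021). In SALK_070989 WRKY1 was near the lowest value of 2.23 in light (2.25) and dark (2.37), so this value mostly restates the fall in Col-0. The call on WRKY1 ended without Col-0 dark replicate 3, SALK_070989 dark replicate 3 or Col-0 light replicate 2 (1.07, 0.97 and 1.07, with adjusted p = 0.051, 0.084 and 0.054). The count was 180 without SALK_070989 dark replicate 3, 148 and 205 without Col-0 light replicates 1 and 2, and 490 in a fit to only these groups.

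In the dark, nitrogen supply changed 2879 probe sets in Col-0, 1508 higher and 1371 lower, and 952 by at least 2-fold. AT3G07350 rose by 4.07 ± 0.32 (limma adjusted p = 3.9e-12), the glutaredoxin genes AT4G15690 and AT3G62930 by 3.77 and 3.27, AT5G10210 by 3.38 and GAT1_2.1 by 3.29 ± 0.43. AT4G17670 fell by 3.75 ± 0.30 and AT5G53420 by 2.88 ± 0.21. All 3 nitrate response genes rose (3 adjusted over the list alone), AT1G25550 by 2.77 and AT1G68670 by 2.84 (camera adjusted p = 3.3e-09, and 6e-05 with an estimated correlation). Of 9 dark and carbon starvation genes 6 rose (6 adjusted over the list alone), MCCA by 1.82 ± 0.21 and MCCB by 1.52 ± 0.14 (camera adjusted p = 3.5e-06, and 0.0099 with an estimated correlation). Of 30 nuclear photosynthesis genes 15 rose, PSB27 by 0.77 ± 0.09 and CHLM by 0.88 ± 0.10, but the list's camera call (adjusted p = 1.5e-07) was lost, at adjusted p = 0.072 with an estimated correlation. Of 24 defence genes 7 fell and 1 rose, MYC3 by -1.04 ± 0.17 and CML41 by -1.65 ± 0.31 (camera adjusted p = 0.0093, but adjusted p = 0.093 with an estimated correlation). Without Col-0 dark N-absent replicate 1, the array with the GAPDH bias of 2.91, the nitrate response and the dark and carbon starvation lists kept their calls (adjusted p = 1.3e-05 and 0.016 with an estimated correlation), and the call of the defence list ended (camera adjusted p = 0.05). The total was 1719 without this array, 1912 without Col-0 dark N-rich replicate 1 and 445 in a fit to only these groups.

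SALK_070989 responded to nitrogen in the dark with 4081 probe sets, 1937 higher and 2144 lower, and 816 by at least 2-fold; 4013 remained without the probe sets that were over 4-fold higher in the mutant. AT5G10210 rose by 4 ± 0.22, AT3G62930 by 3.89 ± 0.18, GAT1_2.1 by 3.71 ± 0.35 and AT4G15690 by 3.69 ± 0.19. AT1G27990 fell by 3.37 ± 0.19, LEA by 3.18 ± 0.20 and AT4G17670 by 3.04 ± 0.25. All 3 nitrate response genes rose (3 adjusted over the list alone; median 1.90; camera adjusted p = 9.4e-08, and 0.00018 with an estimated correlation). HYH rose by 3.3 ± 0.19. Across probe sets the responses of the genotypes correlated at r = 0.6, with 1346 called in both in the same direction and 119 in opposite directions.

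This response differed between the genotypes in 1363 probe sets, 496 higher and 867 lower in SALK_070989, and 557 by at least 2-fold. Without the probe sets over 4-fold higher in the mutant 1303 remained. AT5G51440, a small heat shock protein gene, responded more positively by 2.58 ± 0.46 (limma adjusted p = 3e-04), AT1G57630 by 2.47 ± 0.38 and EFR by 2.23 ± 0.36 (7.9e-05). AT1G27990 led the other direction at -3.38 ± 0.29, followed by LEA at -3.18 ± 0.31 and the oleosin gene AT2G25890 at -2.99 ± 0.27, both of the seed-type list. In Col-0 these 3 were at the lowest value of 2.23 in both dark conditions, so their values restate the fall within SALK_070989, and no Col-0 response could be measured. Of the 1363, 27 were of this kind (every Col-0 mean within 0.1 of the lowest value), all lower. Of 30 nuclear photosynthesis genes 15 were lower, at a median of -0.52 (camera adjusted p = 5.8e-12, and 0.037 with an estimated correlation), with PSB27 at -1 ± 0.11 and CHLM at -1.13 ± 0.13. RCA, SBPASE and PRK of the Calvin cycle list, and CHLM, CHLI2 and PORB of the chlorophyll synthesis list, are also among these 30. The calls of those lists, which follow, are therefore not separate results. Of 4 chlorophyll synthesis genes 2 were lower (3 adjusted over the list alone; camera adjusted p = 0.0016, and 0.042 with an estimated correlation), and of 3 Calvin cycle genes 2 (3 adjusted over the list alone; camera adjusted p = 0.0016, and 0.043 with an estimated correlation), with RCA at -0.69 ± 0.13. Of 24 defence genes 4 were higher, EFR and OPCL1 by 2.23 and 1.51 ± 0.26 (camera adjusted p = 0.00084, and 0.042 with an estimated correlation). MCCB was at -1.30 ± 0.18 and MCCA at -1.47 ± 0.27, among 3 of 9 dark and carbon starvation genes that were lower (4 adjusted over the list alone; camera adjusted p = 0.014, but adjusted p = 0.13 with an estimated correlation). Without Col-0 dark N-absent replicate 1, the array with the GAPDH bias of 2.91, the calls of these lists held at the preset correlation but not with an estimated one. The photosynthesis list then had adjusted p = 0.1 with an estimated correlation, and the chlorophyll synthesis, Calvin cycle and defence lists each adjusted p = 0.11. The count was 738 without this array, 769 without Col-0 dark N-rich replicate 1, and 360 in a fit to only these groups.

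The last question was whether the nitrogen response differed between the dark and the light. The dark and light arrays come from the combined and the nitrogen experiment, and the comparison does not separate darkness from the experiment. In Col-0 it differed in 1648 probe sets, 923 higher and 725 lower in the dark. GAT1_2.1 responded more positively in the dark by 3.26 ± 0.56 (limma adjusted p = 1e-04), AT1G70270 by 3.11 ± 0.27 and AT2G32150 by 2.84 ± 0.24. AT1G05575 was at -4.81 ± 0.34 (5.2e-12), AT1G22810 at -4.73 ± 0.38 and PUB19 at -3.22 ± 0.57. Of 9 dark and carbon starvation genes 6 were higher (6 adjusted over the list alone), MCCB by 1.47 ± 0.18 and PPDK by 1.66 ± 0.25, at a median of 0.85 (camera adjusted p = 6.5e-06, and 0.023 with an estimated correlation). WRKY6 and WRKY53 were at -2.50 ± 0.39 and -1.99 ± 0.37. Across probe sets the nitrogen responses of Col-0 in light and dark correlated at r = 0.45. The count was 953 without Col-0 dark N-absent replicate 1, the array with the GAPDH bias of 2.91, 1073 without Col-0 dark N-rich replicate 1 and 503 in a fit to only these groups.

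In SALK_070989 the nitrogen response differed between the same experiments in 1233 probe sets, 597 higher and 636 lower in the dark. CP1, a cysteine protease gene, responded more positively by 4.04 ± 0.42 (limma adjusted p = 1.2e-08), GAT1_2.1 by 3.70 ± 0.50 and AT5G38910 by 3.47 ± 0.58. AT5G16960 was at -4.25 ± 0.28 and LEA4-5 at -3.57 ± 0.59, among 3 of 12 cold and dehydration genes that were lower (camera adjusted p = 0.00087, but adjusted p = 0.22 with an estimated correlation). The other genes of that list to be lower, LEA18 and LEA, are also in the seed-type list. CML37 was at -2.76 ± 0.28. The responses in light and dark correlated at r = 0.52 across probe sets.

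This difference between the nitrogen responses in the dark and the light in turn differed between the genotypes in 285 probe sets, 63 higher and 222 lower in SALK_070989. AT1G49000 was the highest named gene at 2.55 ± 0.54 (limma adjusted p = 0.0081), and AT5G24230 was at 2.18 ± 0.26. AT1G27990 was at -3.39 ± 0.39, AT2G21820 at -3.32 ± 0.62, LEA at -3.18 ± 0.42 and AT2G25890 at -2.99 ± 0.37. AT1G27990, LEA and AT2G25890, and 19 of the 285 in all, were within 0.1 of the lowest value in every Col-0 group compared, so these values restate the difference within SALK_070989 in the dark. Of 30 nuclear photosynthesis genes 7 were lower, CHLM by -1.08 ± 0.18 and PSB27 by -0.87 ± 0.15 (camera adjusted p = 1.1e-07, but adjusted p = 0.095 with an estimated correlation). MCCB was at -1.37 ± 0.24, 1 of 2 lower dark and carbon starvation genes of 9 (3 adjusted over the list alone; camera adjusted p = 0.0026, but adjusted p = 0.095 with an estimated correlation). The count was 113 and 184 without dark N-absent replicate 1 of Col-0, the array with the GAPDH bias of 2.91, and of SALK_070989, 168 and 499 without Col-0 dark N-rich replicates 1 and 2, 435 and 172 without SALK_070989 dark N-rich replicates 1 and 3, and 48 in a fit to only these groups.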

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

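The tests of the 3 patterns weighed here were chosen only after the results were seen, as were the splits with additive effects removed; the other tests of splits were planned.

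The response to nitrogen differed between SALK_070989 and Col-0 in 26 probe sets by limma's test of the interaction. Of 100 splits of the arrays, 31 called at least as many, up to 1863 in another split, but these splits carry the genotype effect itself and give no reference without change. With the additive effects of genotype and nitrogen removed before splitting, 22 of 100 did, with 193 as the highest other, so chance is not excluded.

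The response to darkness differed between the genotypes in 317 probe sets. Of 100 splits 2 called as many, the real one included, with 857 as the highest other, though these splits too carry the genotype effect. With additive effects removed only the real split, 1 of 100, reached 317, and the highest other gave 25, so chance is excluded at a share of 0.05.

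In the dark the nitrogen response differed between the genotypes in 1363 probe sets, a comparison with 2 Col-0 arrays per group and no test of splits. The nitrogen response in the dark differed from that in the light in 1648 probe sets in Col-0, again with 2 arrays in each dark group. In SALK_070989 it differed in 1233, and 13 of 100 splits gave as many, up to 5011, but those splits carry the nitrogen effect itself and decide nothing. With additive effects removed 1 of 100 did, the real one, and the highest other gave 371, so chance is excluded at a share of 0.05. The interaction of nitrogen, light and genotype called 285. In these 3 comparisons darkness cannot be told apart from the experiment, since the dark and light arrays come from separate ones and the timing of the combined treatment is not given in the sources used here.

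The pattern most open to follow-up was the seed-type transcripts that were higher in SALK_070989 in dark N-absent and dark N-rich. Darkness alone, as given in the light experiment, is argued against as the source of the difference between the genotypes. The median difference between the genotypes over the 19 measured genes in dark alone was 0. Darkness did raise some members in both genotypes, such as AT5G01670, from 4.8 to 7.01 in Col-0 and from 4.56 to 7.03 in SALK_070989. Most members stayed near the lowest value. The length of darkness in the combined treatment is not given, so a different length is not covered. Seed material of one fixed makeup in both conditions is argued against too: over 10 members above 5 in both, the difference between the conditions spanned 2.31, from -0.02 for ICL to 2.28 for AtLEA4-1, with a median SE of 0.2. Material not tied to the genotype may contribute and stays open, because 15 of 29 probe sets more than 8-fold higher in the mutant were higher by over 0.3 in Col-0 dark N-rich replicate 2 than in replicate 1, and 0 were lower, against 15.1% and 16.3% of all kept probe sets (no test was run on these 2 arrays). An effect of the genotype also stays open and untested, since 1 insertion line was grown in the combined conditions.

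In a further pattern the effect of SALK_070989 in the light had a small part in the direction of Col-0 darkness, taken as the Col-0 combined minus the Col-0 nitrogen arrays, which also differ by experiment (r = 0.68 across probe sets with dark against light in Col-0). The part was 9.4% of that difference on full medium and 9% in the light experiment, while across probe sets the effect correlated with it at only 0.3 and 0.36. Displaced Col-0 steady arrays are argued against as the whole cause by the 9 found with separate Col-0 arrays. RNA quality is not settled. The GAPDH 3′ bias of the light groups differed by 0.02, but the Actin 3′ bias was 5.9 in Col-0 light and 5.81 in SALK_070989 light. The Actin values of these arrays did not overlap. The dark groups of the light experiment were lower still, at 5.42 in Col-0 and 5.47 in SALK_070989. In the Col-0 groups that define the direction, the Actin bias was not lower in the dark. It was 6.41 in dark N-absent against 6.33 in N-absent, and 6.05 in dark N-rich against 6.02 in N-rich. A shift graded by the measured WRKY1 level of each line is argued against: SALK_016954, at the lowest level (2.26), shifted by 1.2%, SALK_136009 (4.22) by 5.9% and SALK_070989 (2.57) by 9.4%, and the pair with a resolved order of levels, SALK_016954 and SALK_136009, differed by -4.7 ± 1.7 points, although 1 array of each overlapped. A difference in light received or harvest time may also have contributed and was not tested, and an effect of the insertion stays open.

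The last pattern was change in most conditions, best seen in AT4G20300, which was lower in SALK_070989 in all 7. Loss of WRKY1 acting alike in all 3 lines is argued against for this gene, at -0.14 in SALK_136009 and -0.09 in SALK_016954 on full medium, against -1.67 ± 0.14 in SALK_070989. A change carried by the SALK_070989 line alone may account for it and stays open. For the wider set, 15 probe sets called in at least 4 of the 6 other conditions and on full medium in SALK_070989, WRKY1 left out, loss of WRKY1 in all 3 lines cannot be told from line effects: in 5 (33.3%) the estimates of both other lines were at least 0.5 times that of SALK_070989, and in 9 within 2 SE.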

How the results depend on the processing

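The counts without both N-absent arrays numbered 3, and those without the probe sets over 4-fold higher in the mutant (2773 in dark N-absent, 658 in dark N-rich, 4013 and 1303 for nitrogen in the dark in SALK_070989 and its difference), and the list tests without Col-0 dark N-absent replicate 1, were chosen only after the result was seen; the other tests of settings were planned. No named gene, list call or correlation reversed under the settings run for it. The larger side of a count did turn under some settings, as for SALK_070989 steady (801 higher and 983 lower), with 921 and 815 after quantile normalization, 356 and 289 with only the groups compared and 721 and 480 without its replicate 3. With a filter at 6, a further quantile normalization, eBayes with trend and robust settings, or the replicate block, all 23 counts stayed within 1.5 times. Without a filter the genotype effect in dark alone moved, to 648 (the cause was not tested). With an estimated correlation 31 of 104 list calls held. Leaving out Col-0 dark N-absent replicate 1 leaves a single array in that group. At the preset correlation some list calls then ended in dark N-absent and for the nitrogen response in the dark in Col-0. Some also ended for its difference from the light in Col-0 and for the interaction of nitrogen, light and genotype. None ended for the difference in nitrogen response in the dark between the genotypes or for the mean of 7 conditions. Of 1158 values of named genes, calls ended for 80 without a filter, 21 after quantile normalization, 7 with trend and robust settings, 38 with the block and 449 with only the groups compared; with 1 array left out calls ended in 1111 of 10419. Signal near the lowest value of GCRMA limits what can be measured for transcripts absent in one group.

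A fit to only the groups compared has fewer arrays and residual degrees of freedom, and 17 counts moved. It gave 20 for SALK_016954, 433 for SALK_136009, 645 for SALK_070989 and 191 for all 3 lines on full medium. For SALK_070989 against Col-0 it gave 0 in N-absent (limma; 2202 at an unadjusted p under 0.05), 1 in N-rich, 12 in dark, 1251 in dark N-absent and 68 in dark N-rich. The nitrogen response gave 1495 in Col-0, 1326 in SALK_070989 and 0 for their difference (limma; 1208 unadjusted), and the dark response 490 for its difference. In the dark the nitrogen response gave 445 in Col-0 and 360 for the difference between genotypes. It differed between dark and light in 503 in Col-0, and the interaction of all 3 factors gave 48. Without both N-absent arrays numbered 3 the N-absent count was 465 (the cause was not tested).

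With 1 array left out in turn, the counts ranged from 184 to 698 for SALK_016954, 636 to 1024 for SALK_136009, 1201 to 1810 for SALK_070989 steady and 164 to 382 for all 3 lines. They ranged from 508 to 1473 in N-absent, 150 to 550 in N-rich, 218 to 341 in dark, 436 to 668 in light, 1286 to 2675 in dark N-absent, 479 to 777 in dark N-rich and 2762 to 3286 for the mean of 7 conditions. The nitrogen response ranged from 2749 to 3732 in Col-0, 1958 to 2590 in SALK_070989 and 17 to 112 for their difference. The dark response ranged from 10545 to 10597, 10199 to 10305 and 148 to 280, and the nitrogen response in the dark from 1719 to 2437, 3031 to 3779 and 738 to 1539. The difference in nitrogen response between dark and light ranged from 953 to 1642 in Col-0 and 962 to 1232 in SALK_070989, and the interaction of all 3 factors from 113 to 499. The correlations ranged from 0.61 to 0.67 for steady and light, 0.73 to 0.78 for nitrogen, 0.97 to 0.98 for darkness and 0.54 to 0.62 for nitrogen in the dark. Where a single Col-0 array was left in a group, it was assumed to vary like the other groups. The cause of these ranges was not tested.

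Replicate numbers were not taken to pair the arrays, since in each experiment some arrays of the same number correlated below 0. The lowest values were -0.27 in steady, -0.1 in nitrogen, -0.07 in light and -0.18 in combined, which does not exclude pairing. As a separate measure, 1 of 12 steady, 8 of 12 nitrogen, 5 of 12 light and 2 of 10 combined arrays correlated best with their own number. The median correlation of same-numbered arrays was -0.05, 0.12, 0 and -0.05, and of other numbers 0.02, -0.07, 0 and 0.02. In the nitrogen experiment, where same-numbered correlations ran from -0.1 to 0.49, this is a hint of shared deviations. With the replicate block the counts included 460 for SALK_016954, 1755 for SALK_070989 steady, 573 in dark N-rich and 21 for the difference in nitrogen response.

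Between 3 and 3 arrays 10 splits cannot give a share under 0.05. The real split, 1 of 10, and the highest other gave 468 and 2 for SALK_016954, 1212 and 3 for SALK_136009, 1784 and 181 for SALK_070989 steady, 1146 and 587 in N-absent, 393 and 15 in N-rich, 372 and 18 in dark, and 802 and 10 in light. They gave 3693 and 183 for the nitrogen response in Col-0, 2688 and 25 in SALK_070989, 10905 and 0 for the dark response in Col-0, 10611 and 1 in SALK_070989, and 4081 and 55 for nitrogen in the dark in SALK_070989. For all 3 lines 2 of 100 splits called as many as 356, the other with 381, which kept the 3 Col-0 steady arrays as the shared group. The count thus sets these Col-0 arrays against the mutant arrays and cannot tell the lines from one another. Chance in the choice of the shared group is excluded at a share of 0.05, but a displacement of these Col-0 arrays is not. For the mean of 7 conditions 1 of 100 did, the real one with 3135 against 264. Chance in the labels of these arrays is excluded at a share of 0.05, but chance between cultures is not.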

Other observations

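None of the tests in this part was chosen after its result was seen.

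For plastid-encoded transcripts no camera call at the preset correlation held with an estimated correlation. Of 66 measured, 23 fell with nitrogen supply in the dark in Col-0, at a median of -1.11 (camera adjusted p = 3.8e-11, but adjusted p = 0.37 with an estimated correlation). In dark alone 3 were lower in SALK_070989 than in Col-0, at a median of -0.55 (camera adjusted p = 4.1e-13, but adjusted p = 0.65 with an estimated correlation). Of 8 tau and phi class glutathione transferases, enzymes of detoxification, 6 fell in darkness in each genotype. Their median was -0.83 in Col-0 (camera adjusted p = 0.027, but adjusted p = 0.13 with an estimated correlation) and -0.94 in SALK_070989 (camera adjusted p = 0.016, but adjusted p = 0.12 with an estimated correlation). The UDP-glycosyltransferases (33 measured), the starch and sugar genes (7) and the iron regulation genes (8) had no camera call in any of the 22 comparisons.

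Counting calls in one direction over the 7 conditions with both SALK_070989 and Col-0, 8529 kept probe sets were called in no condition, 4270 in 1, 1186 in 2 and 257 in 3. Calls in 4, 5, 6 and 7 conditions numbered 30, 11, 2 and 3.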
